A study of Mus musculus with 2 samples.

How the data were processed

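DNA methylation was measured by methylated DNA immunoprecipitation (MeDIP), which pulls down sonicated DNA with an antibody against 5-methylcytidine, followed by hybridization to a CpG island microarray. The series holds 2 arrays, both of BALB/c mouse DNA. The first carried DNA pooled from 2 colon tumors induced with AOM (azoxymethane, a carcinogen) and DSS (dextran sodium sulfate, which inflames the colon). The second carried DNA pooled from 2 samples of normal colonic epithelium, taken as isolated crypts from untreated animals. On each array the immunoprecipitate was labelled with Cy5 and sonicated input DNA of the same pool with Cy3, per the labels. No dyes were swapped. Each array therefore compares a pool with its own input, and the contrast between tumor and normal is a difference between the arrays. With 1 array per pool there is no replicate, the spread between animals is unknown, and no p-value is given.

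The deposited table gives 1 log2 ratio per probe and array for 97651 probes. Feature extraction used Agilent Feature Extraction 9.1, per the submitters' processing notes; other steps are not given in the sources used here. The base of the logarithm was read from the values. The most frequent entries were log2 of ratios of small whole numbers plus a constant. With that constant, 78.8% of the tumor array's values and 79.7% of the normal array's were ratios of whole numbers, the smaller at most 300, within a relative tolerance of 3e-07. A slightly shifted constant gave 4.47% and 4.95%. The constants correspond to factors of 0.593 and 0.518, 1 per array, so the values behave as ratios of whole-number signals scaled by 1 factor, whose origin is not given in the sources used here. No correction that depends on intensity was seen in them. Whether the factor of each array served to bring both to a similar centre, with deposited medians of 0.11 and 0.15, is not known. The whole numbers are in lowest terms and so are lower bounds on the signals.

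Which channel is on top is not stated. Among probes with a recovered ratio, the median numerator on the tumor array went from 6 at levels under -4 to 1082 at levels from 2 to 4, while the median denominator stayed between 85 and 106. On the normal array the numerators went from 7 to 1272 and the denominators stayed between 88 and 111. The numerator thus carried nearly all of the variation, which is what an immunoprecipitate over its input would give. With the dyes in the labels, immunoprecipitate over input is the likely direction, and for the same probe a higher value is read here as more methylated DNA. Levels were not set against known methylation, so they are enrichments, not methylated shares. Upper runs and transitions below are therefore classes of enrichment, and levels of different runs are not a ranking of methylation. If the ratio ran the other way, every "higher" and "lower" difference would change places. The rules given below for upper runs and transitions treat high and low levels unequally, so they would pick other runs, not counted here.

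The files used here do not pair the probes with genes or positions, and 0 of the 97651 probe identifiers matched the mouse gene table of assembly GRCm38.p6. The 15 lists of 849 genes that had been set, among them markers of epithelial, immune and stromal cells, and the comparison of X-linked with autosomal probes were therefore not analysed here. In their place, probes were joined into runs wherever their identifiers had consecutive numbers, a choice made after seeing the data. Neighbouring numbers carried related values. Across pairs of probes, the correlation of levels was 0.36 on the tumor array and 0.38 on the normal array for consecutive numbers. It was 0.32 and 0.33 for numbers 2 apart, 0.34 on both arrays for numbers 3 to 20 apart, 0.14 and 0.11 for 21 to 100, and 0.03 on both for numbers over 1000 apart. Differences between the arrays correlated less, at 0.27 for consecutive numbers, 0.23 for 2 apart, 0.16 for 3 to 20 and -0.004 for 21 to 100. Breaking runs at each missing number therefore splits some related probes. A run is a stand-in for part or all of an island, not a mapped region.

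Each array was centred on its median, and the difference was the tumor value minus the normal value. Rules, gene lists and alternatives were fixed before the data were examined, except where stated. The rule for differences counted differences of at least 1 on the log2 scale, a 2-fold difference, for probes and for means over runs of at least 3 probes. The rule for transitions took runs in the lowest 50% of one pool and the highest 10% of the other. Named probes were, by rule, the 2 with the largest and the 2 with the smallest difference. Its part for genes was applied to runs, as the 12 with the largest and the 12 with the smallest mean difference among runs whose probes all had the same sign. The spread given for a run is the SD over its probes; it describes these arrays and not the animals. A level of 1.5, near the dip between the groups of levels, was set after seeing the data to part off upper runs.

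The difference of each probe was shuffled 100 times among probes of similar level (20 bins) to see how many runs would pass without the relation between neighbours. The shuffled differences include those of any truly changed probes, so they are not noise alone. The same code was tested on simulated data, with shuffled differences in 15213 runs and 200 changed runs. It recovered 99% of the 100 runs changed by 1.5 and 100% of the 100 runs changed by 2.5, and called 23 unchanged runs higher and 11 lower. Both sizes lie above the limit of 1, so this checks the code and not the power near the limit. The calls of unchanged runs hold for independent probe differences only, as shuffling removes the relation between neighbours. The alternatives were no centring, scaling by the median absolute deviation (MAD), quantile normalization, other limits, medians over probes, other minimum numbers of probes, and odd or even probes of each run alone, counted in order. Alternatives added after seeing the data left out dim probes (a recovered whole number, in lowest terms, of 20 or less on either array), dim denominators, or the most extreme probe of each run; joined numbers up to 2 or up to 20 apart; or took the median difference of probes of similar level (20 bins) from each probe. Computations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9. The number of arrays limits the precision of every value.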

Results

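The CpG island methylation of AOM/DSS-induced mouse colon tumors was compared with that of normal colonic epithelium, on 1 array of pooled DNA each, to find islands whose methylation differs in the tumors. There are no replicates. The tumor array gave a value for 97455 of 97651 probes and the normal array for 97456, and 97290 probes had both. The deposited medians were 0.11 on the tumor array and 0.15 on the normal array, and the interquartile ranges were 1.73 and 1.81. Levels below are log2 ratios, likely of immunoprecipitate over input, relative to each array's median. Probes with consecutive numbers formed 21933 runs, of which 15213 had at least 3 probes with both values. These runs held 87648 probes, with a median of 5 per run.

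In both pools the runs fell into a large group of low enrichment and a small group of high enrichment. The median level of all runs was -0.21 in the tumor pool and -0.22 in the normal pool. Upper runs, with a level of at least 1.5, numbered 1060 in the tumor pool, or 6.97%, and 1089 in the normal pool, or 7.16%. Of these, 1013 were upper runs in both pools. Their median level was 2.26 in the tumor pool and 2.22 in the normal pool. A dip separated the groups. Levels from 1.4 to 1.6 held 112 runs in the tumor pool and 94 in the normal pool, against 193 and 263 at levels from 2.2 to 2.4.

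**Figure D1:**
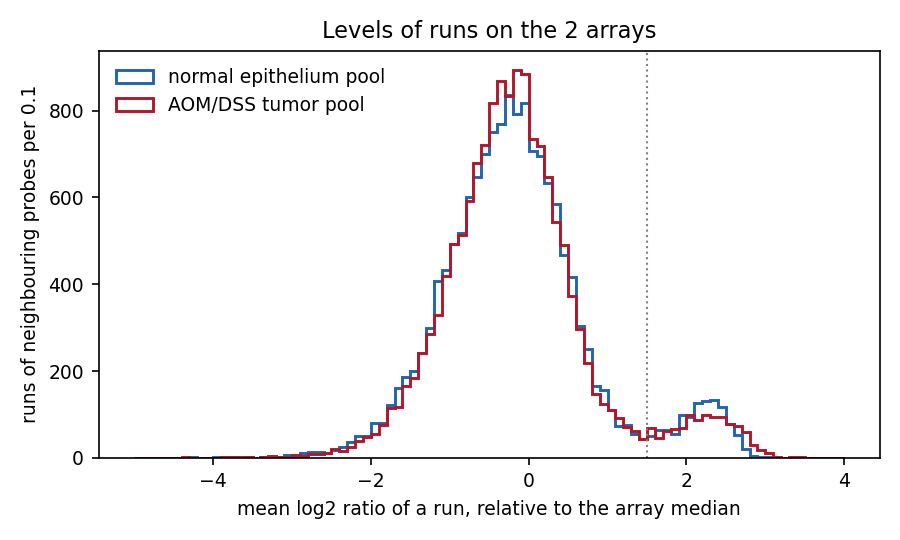
Histogram of the mean log2 ratio of 15213 runs of neighbouring probes on each array, relative to the array's median (x axis) against the number of runs per bin of 0.1 (y axis). Both pools show a large group of runs around -0.2 and a small one above the dotted line at 1.5, with 1060 runs there in the tumor pool and 1089 in the normal pool.

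Runs that were highly enriched in normal epithelium were, with few exceptions, highly enriched in the tumors too. Among the 1013 runs in the upper group of both pools, the difference had a median of 0.06 with an SD of 0.20 across runs, 1 run was at least 1 higher in the tumor pool and 0 were at least 1 lower. Of the upper runs of the normal pool, 76 had a level under 1.5 in the tumor pool, and 5 of them were at least 1 lower there. Of the upper runs of the tumor pool, 47 were under 1.5 in the normal pool, and 9 of them were at least 1 higher in the tumor pool. At the very top the tumor array read higher. The 219 runs with a mean level of 2.5 or more differed by a median of 0.18, against a median of 0.02 for the 213 such runs after quantile normalization of the arrays.

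The profiles of the pools were close overall. Across the 97290 probes with both values, Pearson's r was 0.94 and Spearman's rho 0.95, and across the 15213 runs r was 0.95. These are correlations across probes and runs, which are not independent replicates. Signal differences between probes that both arrays share raise them, and were not separated here from methylation. The scaled MAD of the difference was 0.31 for probes and 0.22 for runs. Of the probes, 96.0% differed by less than 1, as did 15064 of the 15213 runs.

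More runs were higher than lower in the tumor pool. A mean at least 1 higher, or 2-fold, was found for 116 runs (0.763%) and a mean at least 1 lower for 33 runs (0.217%). All probes had the same sign in 93 of the 116 higher runs and in 22 of the 33 lower runs. Every probe was at least 0.5 higher in 56 runs and at least 0.5 lower in 7. Shuffled probe differences gave 24.4 higher and 11.4 lower runs on average, with highest values of 36 and 19 in 100 shuffles. The counts in both directions depended on how probes were joined and summarised. Against 116 higher and 33 lower, joining numbers up to 2 apart gave 107 and 15, and up to 20 apart 86 and 10. Medians gave 102 and 18, and leaving out dim probes 80 and 12. Without the most extreme probe of each run, 56 were higher and 4 lower, as that removes the largest difference by construction. Other settings brought the counts closer together. On odd probes 173 runs were higher and 68 lower, and on even probes 164 and 87. These rest on fewer probes per run than the main counts. They also differ from the split given below, which took only runs with at least 2 probes of each kind. At a limit of 0.75 the counts were 234 and 100, and with a minimum of 1 probe 260 and 166.

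The higher runs were spread over low and middle levels. By the mean level of both pools, 68 of the 116 (58.6%) lay under 0, against 9437 of all 15213 runs (62.0%). The share of higher runs had no steady trend with the mean level. It was 1.02% under -1, 0.627% from -1 to 0, 0.939% from 0 to 1, 1.42% from 1 to 1.5 (5 of 351 runs) and 0.238% from 1.5 to 2.5, and at 2.5 and over it was 0 of 219 runs. The excess over lower runs lay mostly at middle levels, with 45 higher against 9 lower from -1 to 0 and 41 against 5 from 0 to 1. Under -1 the counts were closer, 23 against 15. From 1 to 1.5 they were 5 against 3, and from 1.5 to 2.5 they were 2 against 1. The levels in each pool partly follow from selecting runs by their difference. The median level of the higher runs was -0.90 in the normal pool, with quartiles of -1.48 and -0.36, and 0.63 in the tumor pool, with quartiles of -0.04 and 1.05. The median difference was 1.31, and 9 runs differed by at least 2. In the tumor pool 10 of the 116 had a level of at least 1.5. The lower runs had a median level of -0.13 in the normal pool and -1.46 in the tumor pool, and 5 of the 33 had been upper runs in the normal pool. Their probes scattered more, with a median SD over the probes of a run of 1.46, against 0.84 in the higher runs.

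**Figure D2:**
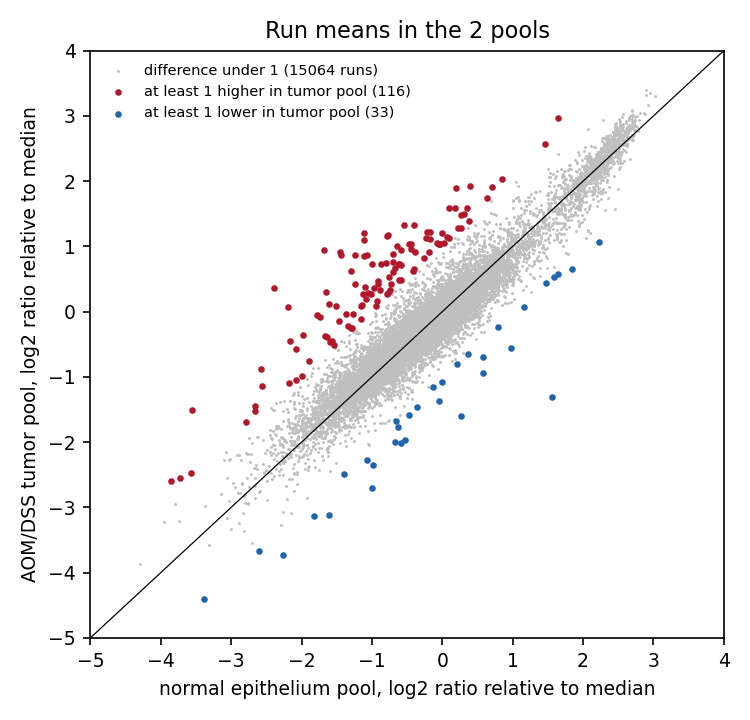
Mean log2 ratio of each run in the normal pool (x axis) against that in the tumor pool (y axis), both relative to the array's median, with the line of equality. Red points are the 116 runs at least 1 higher in the tumor pool, blue points the 33 runs at least 1 lower and grey points the other 15064.

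Of the runs with all probes on the same side, the 12 with the largest differences were between 1.95 and 2.75 higher in the tumor pool. They held 3 to 5 probes each. Their levels ranged from -3.56 to -0.77 in the normal pool and reached 1.21 in the tumor pool. Their SD over probes ranged from 0.15 to 2.02, so some of them were uneven. The largest, over 5 probes, was 2.75 ± 0.72 higher (SD over probes), with a mean of -2.38 in the normal pool and 0.37 in the tumor pool. The next, over 3 probes, was 2.62 ± 2.02 higher, with single probes from 0.30 to 3.80 higher. A run of 4 probes was 2.32 ± 0.47 higher, going from -1.11 to 1.21, and a run of 3 probes 2.36 ± 0.18 higher, from -1.45 to 0.92. The 12 most strongly lower runs had differences from -1.70 to -1.10, and in 6 of them the SD over probes exceeded the mean difference, against 0 of the 12 higher runs. Among these 12 lower runs the smallest SD belonged to a run of 5 probes, whose level was 1.85 in the normal pool and 0.65 in the tumor pool, a difference of -1.20 ± 0.44.

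**Figure D3:**
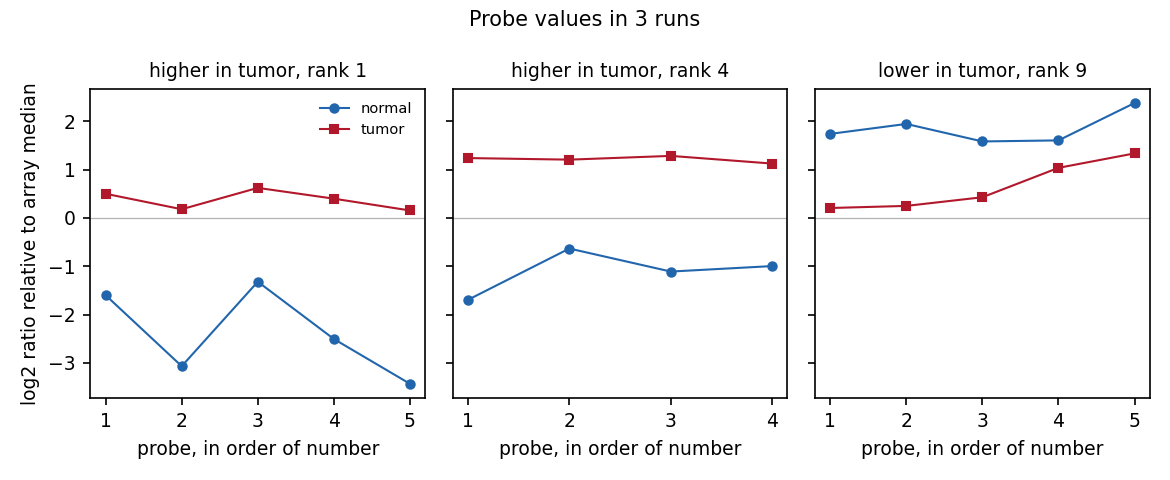
Log2 ratio relative to the array's median (y axis) of each probe, in order of probe number (x axis), for the normal pool (blue circles) and the tumor pool (red squares) in 3 runs. Of the 12 most strongly higher and the 12 most strongly lower runs, up to 2 each with the largest differences were taken among those with at least 4 probes and an SD over probes under 0.5 times the difference, a condition that 1 lower run met: in the higher runs, with mean differences of 2.75 and 2.32, every tumor probe lies above its normal counterpart, and in the lower run, -1.20, every one lies below.

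Runs that went from the lowest 50% of the normal pool to the highest 10% of the tumor pool numbered 14. The opposite change was found in 2 runs. The 14 had a median level of -0.56 in the normal pool and 1.11 in the tumor pool, and differences from 1.36 to 2.62. Their tumor levels, from 0.94 to 1.33, were below 1.5 in all 14. With stricter limits, the lowest 40% and the highest 5%, there were 0 runs of either kind, and the 2 runs high in the normal pool only became 0 with medians over probes and 1 without dim probes.

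Each run was split into odd and even probes, counted in order within the run, over 12089 runs with at least 2 probes of each kind. Both sets came from the same pull-down and array, so noise shared by neighbouring probes would repeat as well. Odd probes placed 120 runs at least 1 higher in the tumor pool; on the even probes these had a median difference of 0.69, and 106 of the 120 were higher. Odd probes placed 38 runs at least 1 lower; on the even probes their median was -0.22, and 29 of the 38 were lower. Chosen on the even probes, 110 higher runs had a median of 0.78 on the odd probes and 46 lower runs one of -0.17. Both sets of probes differed by at least 1 in 45 higher runs and in 3 lower runs. Across the 12089 runs the differences on odd and even probes correlated with r of 0.45.

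By single probes the directions were nearly balanced at the limit of 1. Of 97290 probes, 2130 were at least 1 higher in the tumor pool (2.19%) and 1735 at least 1 lower (1.78%). This order depended on the scaling: after scaling each array by its MAD, 1867 were higher and 1990 lower. Without dim probes, 1079 were higher and 701 lower. With all probes the balance also depended on the limit, with 808 higher and 507 lower at 1.5, and 3920 and 3686 at 0.75. Large differences were most frequent at low levels. Among probes with a mean level under -2, 9.49% were higher and 7.71% lower, against 0.817% and 0.833% at levels from 0 to 1.

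The largest single-probe differences were not shared by neighbouring probes. Probe A_68_P20716448 was 6.84 higher in the tumor pool, and the other 7 probes of its run differed by a median of 0.05. Probe A_68_P32260355 was 6.56 higher, while the 24 others of its run differed by a median of 0.003. Probe A_68_P29482773 differed by -13.3 and its 4 neighbours by -0.20, and probe A_68_P28043320 by -5.90 and its 2 neighbours by 0.14. On the normal array the recovered numerator was 3 for each of the first pair, and the recovered denominator of A_68_P29482773 was 2. For A_68_P28043320 the recovered numbers were larger, 80 over 221 on the tumor array and 2203 over 87 on the normal array. Signal over background was not analysed here, so the sizes and the ranking of these differences are not precise. These probes were not placed in genes here.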

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

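Runs in place of genes, the alternatives without dim probes, dim denominators or the most extreme probe, the joining of numbers up to 2 or 20 apart, and the removal of median differences by level were tests chosen after the data were seen. No paired analysis was possible because each pool has a single array, and no replicate could be left out. Alternatives for the gene lists, for named genes by medians and for X-linked probes were not run, as probes could not be named. In all 16 alternatives for runs the number of higher runs was 1.57 to 14.0 times that of lower runs, against 3.52. The lowest ratios were 1.57 with a minimum of 1 probe and 1.89 on even probes. All 16 reuse the same arrays, and shuffled differences also gave more higher than lower runs. A ratio over 1 in each setting therefore decides little. No centring, MAD scaling and quantile normalization kept the counts of higher and lower probes and runs within 1.5 times, as quantile normalization did those of transitions; after quantile normalization 114 of the 116 higher and 33 of the 33 lower runs still passed. Other limits and minimum numbers of probes change counts by construction. A limit of 1.5 gave 808 higher and 507 lower probes, and 35 and 6 runs; a limit of 0.75 gave 3920 and 3686 probes, and 234 and 100 runs. A minimum of 1 probe gave 260 higher and 166 lower runs, and of 6 probes 19 and 4. Medians over probes gave 102 higher and 18 lower runs, and 0 high in the normal pool only. Odd probes alone gave 173 higher and 68 lower runs and even probes 164 and 87, on fewer probes per run than the main counts. Stricter class limits (lowest 40%, highest 5%) left 0 transitions each way. Leaving out dim probes, a filter that follows the lower of a probe's levels, gave 1079 higher and 701 lower probes. It also gave 80 higher and 12 lower runs and 1 run high in the normal pool only. Joining numbers up to 2 apart gave 107 higher and 15 lower runs, and up to 20 apart 86 and 10. Leaving out the most extreme probe of each run gave 56 higher and 4 lower runs, as it removes the probe with the largest difference by construction; for the others the cause was not tested. The split of probes, 2130 higher and 1735 lower, turned to 1867 and 1990 with MAD scaling. Probe A_68_P29482773 differed by -11.5 after quantile normalization. Recovered whole numbers of 20 or less, which are lower bounds on the signal, were found for 3135 of 4181 probes whose lower level was under -3 and 5687 of 44636 at 0 and over; signal over background was not analysed here.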

Other observations

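The tests of a rise of all low-level probes, of independent probe noise and of chance placement were chosen after the results they bear on were seen, and the settings without dim probes, without dim denominators and with numbers up to 20 apart joined were chosen after the data, with the counts of higher and lower runs, were seen. Probes without a value on a single array were weakly enriched on the other. The 166 probes missing only in the tumor pool had a median level of -3.73 in the normal pool. The 165 probes missing only in the normal pool had a median of -3.23 in the tumor pool, and 30 probes were missing on both arrays. In order of probe number, the last 2 of 65 blocks (1500 probes, and 1290 in the final block) had higher medians than any other block in both pools: 0.34 and 0.42 in the tumor pool and 0.33 and 0.40 in the normal pool, against -0.24 to 0.19 and -0.23 to 0.24 in the other 63. The median difference between pools in those 2 blocks was 0.03 and 0.02, within the range of -0.05 to 0.04 over all blocks. The positions of these probes were not analysed here.

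The excess of higher over lower runs, 116 against 33, was set against technical explanations. After quantile normalization, which removes differences in scale, the ratio was 3.03 and 114 of the 116 higher runs still passed. Without dim denominators the ratio was 4.04 and 87 of 93 testable higher runs passed. With the median difference of probes of similar level taken off, against a rise of all low-level probes, 112 of the 116 passed. That count decides little, since such median differences were small against the limit of 1. By mean level, the median difference of probes was 0.07 under -2 and 0.05 from -2 to -1. A rise of all low-level probes was thus small, and a rise of only some of them was not tested. Shuffled probe differences gave at most 36 higher runs in 100 shuffles, but also 2.13 times as many higher as lower runs. The shuffled values include the probes of the called runs, so this skew may come from noise or from change. Shuffling breaks any noise that neighbouring probes share, so such noise was not tested. Without dim probes the ratio was 6.67, which decides nothing, since that filter follows the lower of a probe's levels and removes the directions unequally. What stays open is noise of dim probes, noise shared by neighbouring probes, and a skew of single probes for part of the ratio. A gain of methylation in the tumors also stays open, which 1 array per pool cannot show to be general. The tumors came from animals given AOM and DSS and the crypts from untreated ones, so tumor and treatment cannot be told apart. Cells of other types stay open too, since whole tumors may hold immune and stromal cells that isolated crypts lack. As 0 probes could be named for marker genes, these explanations cannot be told apart.

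Single probes with differences of 3 or more numbered 158, with 103 higher and 55 lower in the tumor pool. Of these, 79.7% had a recovered whole number of 20 or less on an array, against 20.1% of all probes, but all probes matched on the lower of their levels in bins of 0.5 gave 78.2%, a comparison added after seeing the data. Dim signal and a low level thus cannot be told apart, since a low level by itself brings small numbers. A change of the whole neighbourhood was argued against for most, as the other probes of their runs moved in the same direction by a median of 0.13 (139 probes in tested runs), with a median of at least 1 for 12 of them. No biological explanation was tested.

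Runs that differed lay near each other in probe number more often than random runs, in both directions. Of the 116 higher runs, 8 had another within 100 numbers, and as many were reached in a share of 0.0003 of 10000 random sets; of the 33 lower runs it was 3, with a share of 0.0007, and the median of the random sets was 0 for both. The random sets treat runs as independent, but runs are broken at each missing number. Differences of probes correlated with r of 0.23 for numbers 2 apart, 0.16 for 3 to 20 and -0.004 for 21 to 100. The shares thus argue only against independent placement of the runs as broken here. When numbers up to 20 apart were joined, 86 runs were higher and 10 lower, and 2 of the 86 lay near each other, with a share of 0.108. Chance placement of the joined runs was thus not argued against. Joining merges near runs whatever their origin, so pieces of 1 island and separate neighbouring islands cannot be told apart. No biological explanation was tested.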
